A study of Mus musculus with 10 samples.

How the data were processed

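Gene expression was measured on 10 Affymetrix Mouse Gene 1.0 ST arrays, 5 from haematopoietic stem cells (HSCs) of Sox17-transgenic mice and 5 from those of wild-type littermates. Groups and replicate numbers were taken from the sample titles. Per the labels, the cells were sorted from bone marrow as positive for CD150, Sca1 and cKit and negative for CD48 and lineage markers, 10000 cells per aliquot, and both groups had received doxycycline at 2 mg/ml in the drinking water for 5 days. The RNA was amplified with the WT-Ovation Pico system, turned into sense-strand cDNA and labelled with biotin, per the labels' protocols.

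The authors deposited 1 table of log2 expression values, with a row per probe set and a column per array. Per the submitters' processing notes these values come from robust multi-array average (RMA) processing, with the R packages affy and limma also named; versions and settings are not given in the sources used here. RMA subtracts background, gives all arrays the same intensity distribution at the probe level and summarises the probes of a probe set. Differences between low values are therefore compressed, and a gene near the array's floor can change without a change in its value. The deposited values were used as they stand, with no further normalization, filter or pseudocount. An array has no read depth, and the number of arrays limits the precision.

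The table holds 35556 probe sets. The platform annotation used here pairs 21789 of them with 1 gene symbol and 1621 with several, and 12146 are unnamed here. Symbols were checked through the Entrez identifier against a RefSeq gene table of assembly GRCm38.p6, in which 21698 of the 21789 identifiers were found, and 0 symbols had to be changed. Probe sets with several genes were tested but name no gene. The genome build of the array design is not given in the sources used here, so no coordinates are printed.

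The 23410 probe sets with at least 1 gene symbol were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), transgenic minus wild type, with Benjamini-Hochberg adjustment over all of them and a threshold of 0.05. Gene lists were tested with limma's camera at its preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 25 lists, using for each gene the one-gene probe set with the highest mean over all arrays. Camera with an estimated correlation and fry were run beside it. The lists held 513 entries: 459 had a one-gene probe set, 17 lay on shared probe sets and 37 had no listed probe set, Ly6a, Igf2bp2, H19 and Ddx3y among them. The lists were fetal HSC and oncofetal genes, adult HSC identity genes, sort markers, mitosis, DNA replication, erythroid, globin, megakaryocyte and platelet, granulocyte and monocyte, lymphoid priming, B cell, T and NK cell, mast cell and basophil, endothelial and arterial, stromal, endoderm and Sox17 endodermal targets, Wnt and beta-catenin targets, interferon response, p53 targets, ribosome biogenesis, glycolysis, cholesterol synthesis, oxidative phosphorylation, immediate early genes and imprinted genes. A further list of sex-linked genes served as a check of the arrays.

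Groups, tests, lists, alternative settings and the rule for named genes were fixed before the data were examined. The rule names Sox17, then the 12 highest and 12 lowest log2 fold changes among genes past the threshold (all of them where fewer pass), then up to 4 members of each list with the smallest p, and the sort markers and sex-linked genes as values. Predicted models, clone names, olfactory and vomeronasal receptors and small non-coding RNAs are passed over in the second part.

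The alternative settings were the replicate number as a block, quantile normalization, centring each array on its median, testing only probe sets brighter than the median probe set or all probe sets, eBayes with an intensity trend and robust hyperparameters, limma's array weights, 1 surrogate variable as a covariate, a floor at the 20th percentile of all values, leaving out each array in turn, a threshold of 0.01, a minimum fold of 1.5, a Welch test per probe set, and for the lists the estimated correlation, fry and the mean of all probe sets of a gene. The surrogate variable was computed by the iteratively reweighted method of the package sva, written out in the scripts since the package could not be loaded. A fit with the first principal component of the limma residuals as a covariate, and fits with the 2 sets of arrays described in the results as a block, within each set, and without the 1 male array, were chosen after seeing the data. The limma and list tests were tested on simulated data of 23410 probe sets in 5 against 5 arrays, drawn from the means and spreads of these probe sets with 200 changed. The threshold recovered 43.0% of probe sets changed by 0.5 log2 units, 85.1% of those changed by 1 and 98.2% of those changed by 2, and 6.48% of the calls were unchanged probe sets. With no change simulated, 0 probe sets were called, and a list shifted by 0.5 was called in 100% of the 5 runs, while other lists, not shifted, were called 0.2 times per run. The spread of the simulated probe sets was independent between genes, so these shares do not cover batches. Nor do they cover lists whose genes vary together, such as mitosis with an estimated correlation of 0.54.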

Results

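Gene expression was measured in haematopoietic stem cells (HSCs) of adult mouse bone marrow carrying an inducible Sox17 transgene and in HSCs of wild-type littermates. Sox17 is a transcription factor of endoderm and arterial endothelium on which HSCs depend in fetal and newborn life. The comparison asks what its induced expression changes in adult HSCs, genes of the fetal HSC type among them. Each group had 5 arrays, each from 10000 sorted cells of 8-week-old mice given doxycycline for 5 days, which turns on the transgene through a tetracycline-controlled activator. The aliquots are described as independent without being tied to single animals, so the p-values measure the spread between these samples, which may be technical in part.

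The arrays fell into 2 sets of 5 that did not follow the groups. The first principal component, 35.3% of the variance, parted the transgenic arrays 1, 2 and 3 and the wild-type arrays 1 and 2 (set A) from the transgenic arrays 4 and 5 and the wild-type arrays 3, 4 and 5 (set B). Correlations between arrays across probe sets averaged 0.987 within a set and 0.978 between sets. The sets were defined from these values, by the first component of the deviations from the group means. A fit with the set as a block thus lowers the residual spread by construction, which favours more calls. With the group in the limma model, 2281 probe sets differed between the sets, 1409 of them higher in set B and 872 lower. The RNA component of RNase P (Rpph1) averaged 11.2 in set A and 7.53 in set B, and the histone gene H4c4 averaged 10.8 and 7.13, both chosen after their values were seen. Transgenic array 4 alone read as male, with Xist at 4.32 against 10.8 to 11.4 on the other transgenic arrays and the Y-linked genes Eif2s3y at 9.23, Kdm5d at 7.85 and Uty at 6.97.

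**Figure D1:**
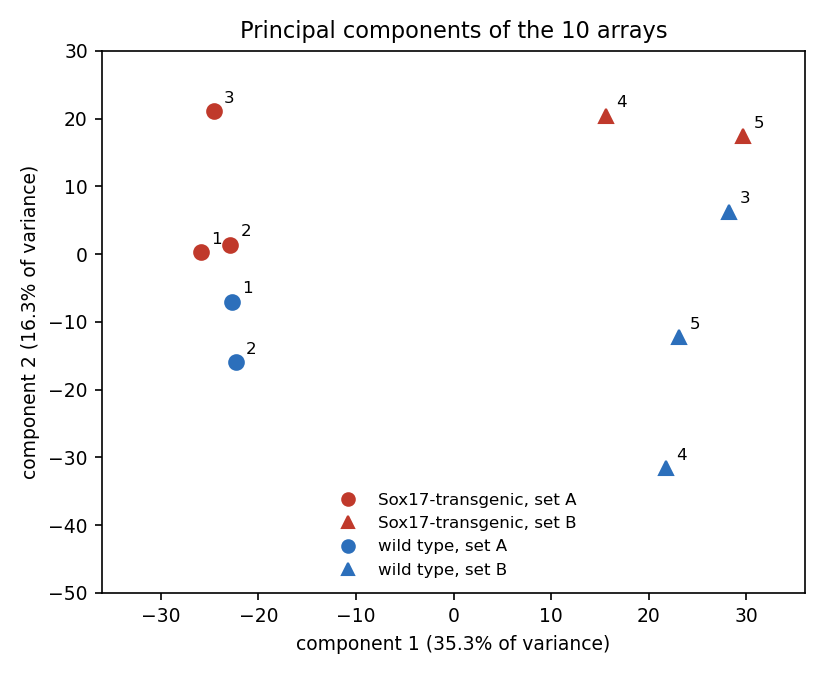
First 2 principal components of the 10 arrays, computed over all tested probe sets (component scores, axes in log2 units), with colour for the group, shape for the set and the replicate number beside each point. Component 1 (35.3% of the variance) parts set A from set B, and each set holds arrays of both groups.

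The Sox17 probe set read close to the array's floor in both groups. It averaged 4.37 ± 0.13 (SD, n = 5) log2 units on the transgenic arrays and 4.21 ± 0.13 (SD, n = 5) on the wild-type arrays, which placed its mean over all arrays at the 23.2 percentile of the tested probe sets. The log2 difference of 0.16 (SE 0.09) did not pass the threshold (limma, adjusted p = 0.855 after Benjamini-Hochberg), and the transgenic arrays ranged from 4.25 to 4.51 against 4.02 to 4.30. A rise in Sox17 was not detectable at this probe set, and the direction of every difference given here rests on the arrays' labels.

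On the arrays labelled transgenic, Cd53, Ccn3, Rasgrp3, Ncam2 and Il10ra rose most, and the platelet gene Pf4 fell most. Of 23410 probe sets, 33 passed the threshold (limma, Benjamini-Hochberg), 28 higher and 5 lower on the transgenic arrays, and 1543 had an unadjusted p under 0.05. With 1 probe set per gene and the 2 probe sets shared by several genes left aside, they came to 25 genes higher and 5 lower. The highest were the leukocyte tetraspanin Cd53, which rose from 6.59 ± 0.68 to 9.37 ± 0.54 (SD, n = 5 each; 6.87-fold, adjusted p = 0.0104), and Ccn3, a secreted matricellular protein, which rose 6.60-fold (adjusted p = 0.00849). Rasgrp3, an activator of Ras and Rap1, had the smallest p: it rose from 4.63 ± 0.17 to 7.32 ± 0.13 (6.45-fold, adjusted p = 4.48e-07). The adhesion molecule Ncam2 rose 5.60-fold and the interleukin-10 receptor chain Il10ra 4.92-fold.

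The other 7 of the 12 highest genes rose by 2.42-fold to 3.78-fold. They were Gimap4, a GTPase of the lymphocyte GIMAP family (3.78-fold), the endothelial surface protein Ecscr (3.27-fold), the growth factor Pdgfc (3.02-fold), Rnd3 (2.67-fold), the glycolysis regulator Pfkfb3 (2.66-fold), the C-type lectin receptor Clec4e (2.50-fold) and the lysosomal protease cathepsin S, Ctss (2.42-fold). All 5 genes that fell are named here. Platelet factor 4, Pf4, fell from 9.41 ± 0.58 to 6.88 ± 0.58 (SD, n = 5 each; log2 change -2.53, adjusted p = 0.0112). The alpha-tubulin Tuba8 fell by 1.36 on the log2 scale. The log2 change was -1.05 for Gfi1b, a transcriptional repressor found in erythroid and megakaryocytic cells, and -0.75 for Fignl1, a DNA repair factor. It was -0.51 for the endoplasmic reticulum lectin Mlec, whose second probe set differed by -0.73 (adjusted p = 0.124). A pair of probe sets shared by several adult beta-globin genes also rose, by 2.22 and 2.04 (adjusted p = 0.0103 and 0.0112), while the 2 probe sets shared by the alpha-globin genes differed by -0.41 (SE 0.39) and -0.38 (SE 0.43) and did not pass the threshold.

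**Figure D2:**
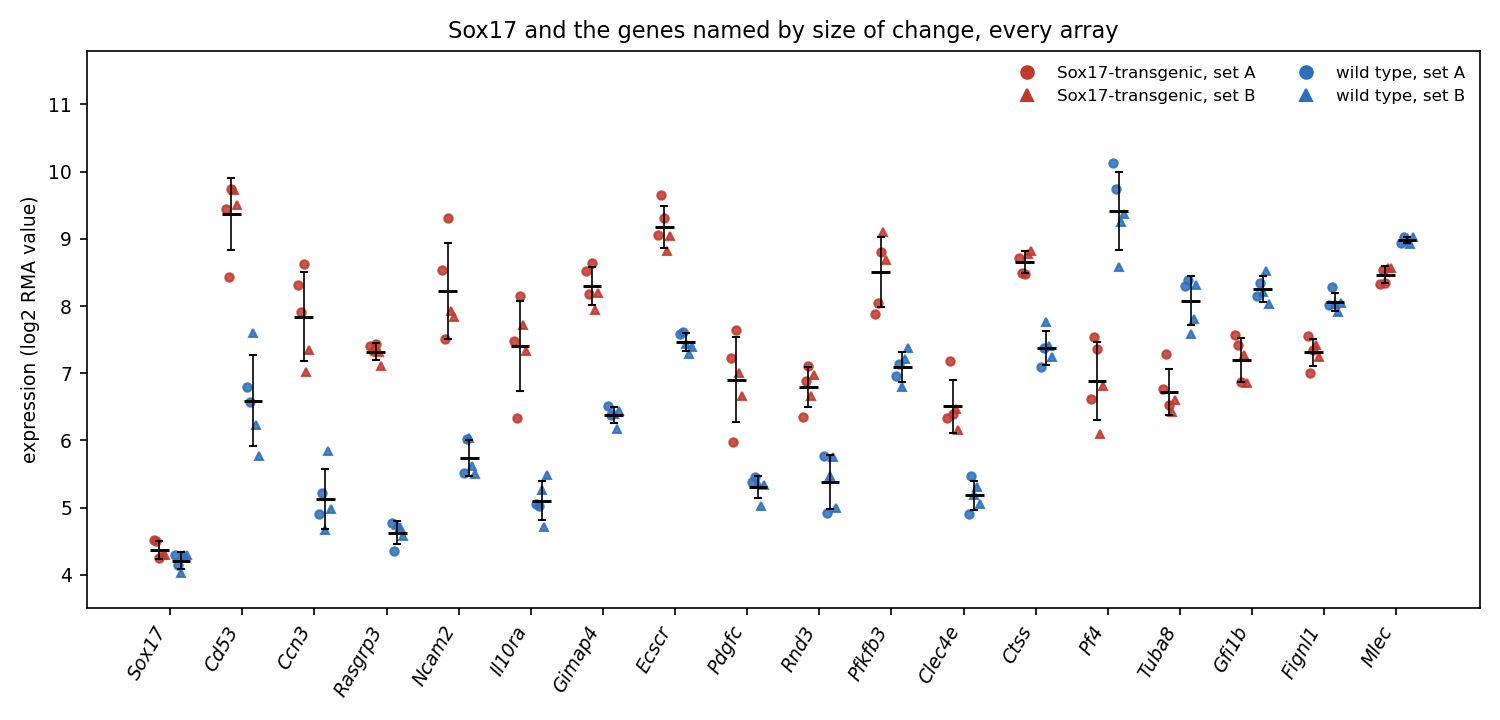
Log2 RMA value (vertical axis) of Sox17 and of the 12 highest and 5 lowest genes past the threshold on each of the 10 arrays, with the group mean and SD as bars, colour for the group and shape for the array set. Sox17 lies between 4.02 and 4.51 in both groups, whereas for each of the 17 other genes the transgenic and wild-type arrays do not overlap.

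In all 33 called probe sets the 5 transgenic arrays lay wholly above or wholly below the 5 wild-type arrays, as in 1.47% of all tested probe sets, where chance alone gives 0.794%. All 33 had the same sign in both array sets, which their lack of overlap gives by construction. With the set as a block 91 probe sets passed (73 higher, 18 lower), these 33 among them. The log2 change was 2.52 in set A and 3.09 in set B for Cd53, 2.83 and 2.54 for Rasgrp3, and -2.77 and -2.61 for Pf4. With fewer arrays, 4 probe sets passed within set A and 6 within set B. Without the male array (transgenic array 4) 15 passed, 14 of them among the 33, and without it and with the block 31, of which 16 were among the 33. Without transgenic array 2 the number was 71, without transgenic array 3 it was 19, and without wild-type arrays 1 to 5 in turn it was 20, 18, 16, 17 and 17.

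Genes of the fetal HSC type were not called. Of 14 measured members of the fetal list, 0 passed the threshold over all genes (limma), 2 had an unadjusted p under 0.05 and 1, Cdh5, passed adjusted over the list alone. The list as a whole was not called (camera, median log2 change 0.06, adjusted p = 0.391). Vascular endothelial cadherin, Cdh5, was 1.48 higher (SE 0.40, adjusted p = 0.305), by 2.24 in set A and 0.55 in set B. It read 7.38 and 7.70 on transgenic arrays 1 and 3, 5.58 to 5.86 on the other transgenic arrays and 4.58 to 5.36 on the wild-type arrays. The Polycomb methyltransferase gene Ezh2 differed by -0.46 (SE 0.15), and Hmga2, a chromatin protein of fetal HSCs, by 0.24 (SE 0.15). Plagl1, which the imprinted list also holds, was 1.10 higher (SE 0.58), with 9.61 on transgenic array 3 and 6.19 to 6.30 on the other transgenic arrays. The adult HSC list rose as a set (26 measured, 15 of them positive, camera adjusted p = 0.0222; adjusted p = 0.180 with an estimated correlation). Gfi1, a transcriptional repressor that restrains HSC cycling, rose 1.56-fold and was the 1 member past the threshold; adjusted over the list alone, 7 members rose and 2 fell. The list's adjusted p was 0.0522 within set A and 0.224 within set B, and 0.0537 without transgenic array 2 and 0.176 without wild-type array 4. Interferon-induced Ifitm1 (0.58, SE 0.11), von Willebrand factor, Vwf (1.28, SE 0.25), and Txnip (0.67, SE 0.15) were higher with adjusted p of 0.0928, 0.110 and 0.157. With the array set as a block Ifitm1 and Vwf passed the threshold too (adjusted p = 0.0301 and 0.0256).

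The sort marker list holds Slamf1, Cd48 and Kit, whose proteins the gate uses, and Flt3, Cd34 and Cd244a, which mark other stem and progenitor fractions and are not in the gate. Flt3, a receptor of multipotent progenitors, read 8.59 ± 0.64 on the transgenic and 7.06 ± 0.54 on the wild-type arrays (SD, n = 5 each; log2 change 1.53, limma adjusted p = 0.132), and Cd48, whose protein the gate excludes, read 6.29 ± 0.53 and 4.96 ± 0.51 (1.34, adjusted p = 0.145). Kit differed by -0.47 (SE 0.12, adjusted p = 0.248), and Cd34, Cd244a and Slamf1 by 0.19, 0.14 and 0.19 with adjusted p of 0.877 to 0.958. As a set the 6 measured markers rose (camera adjusted p = 0.0201; adjusted p = 0.379 with an estimated correlation), with 0 members past the threshold over all genes (limma) and 2 that rose (Flt3 and Cd48) and 1 that fell (Kit) adjusted over the list alone, the same 3 having an unadjusted p under 0.05. The list's adjusted p was 0.350 within set A and 0.00121 within set B, and leaving out transgenic array 4, transgenic array 5 or wild-type array 4 gave 0.0528, 0.0921 and 0.142.

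Genes of DNA replication were lower as a set on the transgenic arrays, while mitosis genes varied more between those arrays. All 30 measured DNA replication genes had negative changes, with a median of -0.37, and the list fell as a set (camera adjusted p = 1.47e-16; adjusted p = 0.0762 with an estimated correlation, and 0.0364 when the array set was also a block). Of its members 0 passed over all genes (limma), 17 had an unadjusted p under 0.05 and 12 fell adjusted over the list alone. Among them, the origin licensing factor Cdc6 differed by -0.72 (SE 0.15), thymidylate synthase, Tyms, by -0.54 (SE 0.14), and the helicase subunit Cdc45 and the initiation factor Mcm10 by -0.68 and -0.45. The mitosis list fell with the preset correlation (28 measured, 26 of them negative, median -0.24, camera adjusted p = 4.97e-05) but was not called with its estimated correlation of 0.54 (adjusted p = 0.526). Its members with the smallest p, Cdk1 (-0.46), Cdca8 (-0.57) and Aurkb (-0.37), had an unadjusted p under 0.05, but 0 members passed over all genes (limma) and 1, Cdk1, adjusted over the list alone. The mitosis scores, means of the list's genes on an array minus their means over all arrays, overlapped between the groups. The highest was 0.39 on transgenic array 1, against at most 0.26 on the wild-type arrays. With the preset correlation the DNA replication and mitosis lists were also called within each array set. In set A, however, transgenic array 1 had a higher mitosis score than both wild-type arrays (-0.01 and 0.21).

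Of 23 erythroid genes 20 had negative changes, and this list's fall was the 1 call that held with an estimated correlation (camera adjusted p = 2.56e-07; adjusted p = 0.0377 with an estimated correlation). The list was called within each array set with the preset correlation. Gfi1b passed over all genes and 9 members adjusted over the list alone; carbonic anhydrase 2, Car2, differed by -0.38, the erythropoietin receptor Epor by -0.46 and the transferrin receptor Tfrc by -0.57. The megakaryocyte and platelet list (17 measured) fell as a set (camera adjusted p = 0.0201; adjusted p = 0.389 with an estimated correlation), but its members split: over all genes only Pf4 passed, and adjusted over the list alone 6 fell and 3 rose. Gp5, a platelet glycoprotein, differed by -1.08 (SE 0.23) and the platelet chemokine Ppbp by -0.97 (SE 0.23), against 1.28 for Vwf, which the adult HSC list also holds. With the array set as a block 2 members fell, Pf4 and Gp5 (adjusted p = 0.00514 for Gp5), and 2 rose, Vwf among them. The list's adjusted p was 0.00311 within set A and 0.224 within set B, and it was 0.148, 0.122 and 0.0827 without transgenic array 5, wild-type array 1 or wild-type array 2. The embryonic globin genes Hba-x, Hbb-bh1 and Hbb-y read 3.28 to 5.59 in group means, with changes of 0.09, 0.08 and 0.05 (globin list adjusted p = 0.334).

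The lymphoid priming list rose as a set (17 measured, 13 positive, camera adjusted p = 0.00674; adjusted p = 0.0844 with an estimated correlation). The chromatin organiser Satb1 rose 1.76-fold (adjusted p = 0.0109) and was the 1 member past the threshold over all genes; adjusted over the list alone 2 rose, Flt3 included, and 1 fell. That 1 was Il12a, a subunit of interleukin-12, which read 6.50 ± 0.48 against 7.51 ± 0.33 (SD, n = 5 each; adjusted p = 0.176 over all genes, and 0.00473 with the array set as a block, which passed). The list's adjusted p was 0.0960 within set A and 0.0651 within set B. The granulocyte and monocyte list was higher (23 measured, 18 positive, camera adjusted p = 0.00228; adjusted p = 0.195 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone (limma) and 2 with an unadjusted p under 0.05. The lysozymes Lyz2 and Lyz1, which are close paralogs, differed by 0.36 and 0.23, S100a8 by 1.24 (SE 0.58) and Cd68 by 0.56 (SE 0.27). Transgenic array 5 was highest in this list, with a score of 0.61 against -0.10 to 0.15 on the other transgenic arrays, and without it the list's adjusted p was 0.0554, S100a8 differed by 0.66 and Cd68 by 0.36.

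The endothelial and arterial list also rose (29 measured, 18 positive, camera adjusted p = 0.00176; adjusted p = 0.379 with an estimated correlation). Egfl7, a secreted endothelial factor, rose 2.32-fold (adjusted p = 0.0260) as the 1 member past the threshold, and 4 rose adjusted over the list alone. Pecam1 (0.68, adjusted p = 0.0591), Cldn5 (0.44) and Cdh5, given above with the fetal list, did not pass over all genes; with the array set as a block Pecam1 did (adjusted p = 0.0469). The list was called within set A (adjusted p = 4.24e-06) and not within set B (0.224). The immediate early genes were higher (21 measured, 19 positive, camera adjusted p = 0.000418; adjusted p = 0.478 with an estimated correlation), with Klf6 at 0.98 (SE 0.23), Egr1 at 0.62 (SE 0.27) and Fos at 0.76 (SE 0.37), 0 members past the threshold over all genes (limma), 2 with an unadjusted p under 0.05 and 1, Klf6, past it adjusted over the list alone. Among the wild-type arrays, 1 and 2 of set A had scores of -0.55 and -0.46 against 0.05 to 0.15 in set B, while the transgenic arrays, at -0.18 to 0.46, were not parted by set. Within set B the list's adjusted p was 0.684.

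**Figure D3:**
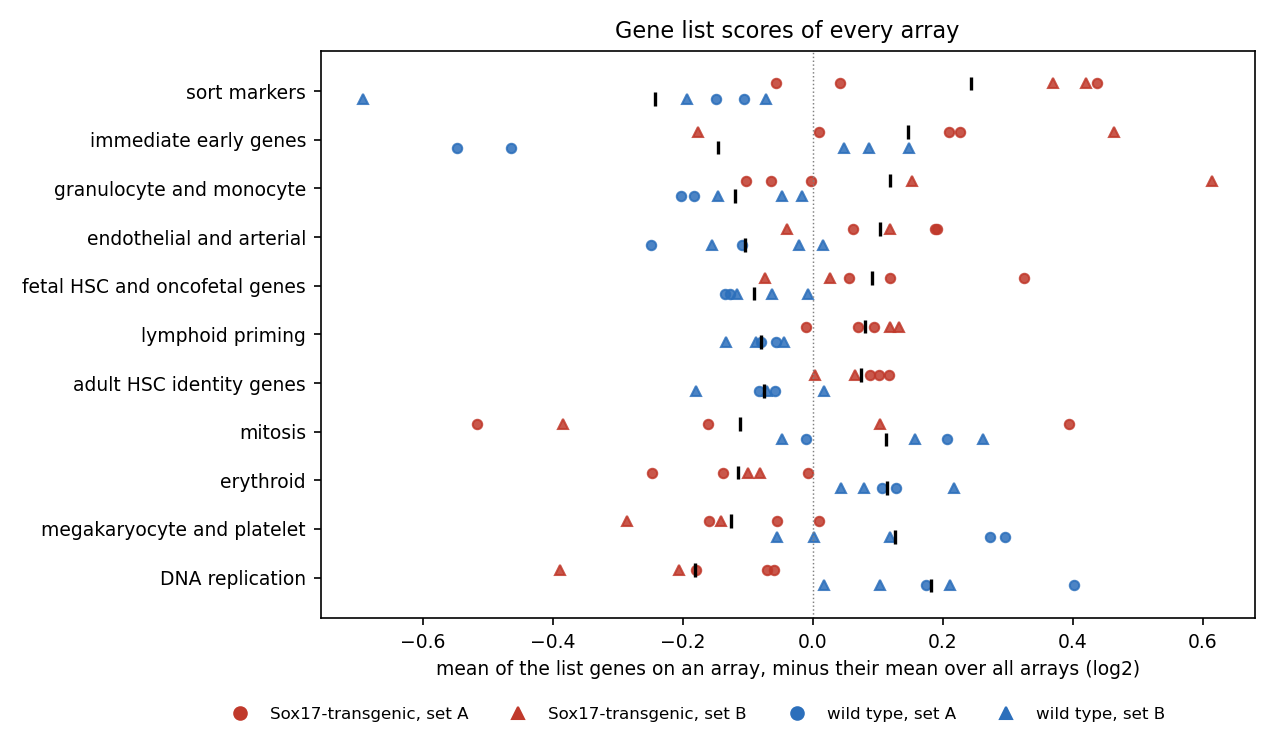
Mean log2 value of a list's genes on each array, minus their mean over all arrays (horizontal axis), for the 10 lists past the camera threshold and the fetal list, with colour for the group, shape for the array set and a bar at each group mean. In the DNA replication list all transgenic arrays lie below all wild-type arrays, whereas in the mitosis list the transgenic arrays range from -0.52 to 0.39.

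The other lists did not pass in camera with its preset correlation. Among them, the Wnt and beta-catenin target list had an adjusted p of 0.0750, with Myc at -0.72 (SE 0.15, adjusted p = 0.145, and 0.0186 with the array set as a block, which passed) and Ccnd1 at -0.68 (SE 0.26), and ribosome biogenesis one of 0.0777; leaving out 1 array gave 0.00821 to 0.295 and 0.00694 to 0.452. With the array set as a block both were called lower, at adjusted p of 0.0196 and 0.0156 (0.424 and 0.440 with an estimated correlation), and the interferon list (adjusted p = 0.553) was called higher at 0.0480 (0.660 with an estimated correlation). Its direction differed between the sets: it was higher within set A (adjusted p = 8.40e-08) and lower, without being called, within set B (0.406). The endoderm list had an adjusted p of 0.382 (0.0233, called higher, among the brighter probe sets), with the matrix protein gene Sparc at 1.54 (SE 0.31). The B cell list (0.579, Vpreb1 at -0.83) and the T and NK cell list (0.701, Nkg7 at -1.17 and Thy1 at 7.88 against 6.68) were not called, nor were mast cell and basophil (0.536), stromal (0.686), p53 targets (0.878), glycolysis (0.553, Slc2a1 at 0.55), cholesterol synthesis (0.663), oxidative phosphorylation (0.218) or imprinted genes (0.770). The medians of the T and NK cell, glycolysis, p53 and cholesterol lists, at -0.01, -0.03, -0.001 and -0.02, had the opposite sign to their means and to the camera test, as did the mean of the B cell list, -0.009.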

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

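In this part the splits of the arrays, the mixed-label test and the quantile test of the array sets were planned before their results were seen. The other tests were chosen after.

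The pattern most in need of a second look is that the Sox17 probe set was not raised on the arrays labelled transgenic, although 33 probe sets differed between the groups. Chance is argued against for the count of 33, though not for each of its members. Of the 126 splits of the 10 arrays into 5 and 5, 100 were run. Only 1 of them, the labelled one, gave as many, and the highest other gave 2. The split by array set, which was not among the 100, gave 2315, which points to a structure of the samples, treated as the second pattern. A mix-up of labels between some arrays would leave a better split. With the array set as a block the labels gave 91 probe sets. Of the other splits with the same number of arrays from each set, among 100 with the labelled one, 0 gave more (the highest gave 2). This argues against a mix-up that keeps those numbers, and against chance for a count of 91, though not for each of its members. A swap that changes the number of arrays from each set was not tested with the block. A swap of all labels at once stays open. A probe set that reads little of the Sox17 messenger remains a possible explanation that cannot be told apart from a low transgene level, since the probe set lay at the 24.7 percentile on the transgenic arrays and no other gene's level bears on it; whether the probes cover the part of Sox17 that the transgene carries was not tested.

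The second pattern is the parting of the arrays into 2 sets, which were defined from these same values, so the number of probe sets that differ between them restates the parting and cannot be set against the 33 of the groups. After quantile normalization 2442 probe sets still differed between the sets (2281 before). This argues only against a difference in overall distribution left in the deposited values. RMA had already aligned the arrays at the probe level, so the test cannot decide on scaling before that step. Sex is argued against by the count of 1 male array. Of 403 histone and small RNA probe sets 61 differed between the sets, 1.57 times the share of other one-gene probe sets (two-sided Fisher's exact test p = 0.000468), but histones carried this excess: 16 of their 30 differed, 15 of them lower in set B, while of the other 373 only 45 did (1.25 times, p = 0.112), 20 higher and 25 lower. Uneven recovery of small and non-polyadenylated RNA thus cannot be told apart from a wider batch difference, as 2056 of the differing probe sets lie outside these classes. Both groups lie in both sets, so no biological explanation from the design was tested.

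The third pattern is the higher Flt3 and Cd48 and the lower Pf4 on the transgenic arrays. With the set as a block Pf4 stayed past the threshold (-2.69, limma adjusted p = 0.000706) and Flt3 and Cd48 kept changes of 1.58 (SE 0.32) and 1.28 (SE 0.29). Each set holds 2 or 3 arrays of each group, so the block could move these changes only a little. For the same reason a difference between the sets could make up only a little of them. Within sets A and B the log2 changes were -2.77 and -2.61 for Pf4, 0.95 and 2.21 for Flt3, and 0.87 and 1.70 for Cd48. These values argue against the array sets as the cause, although Cd48 overlapped between the groups on the arrays of set A. Flt3 and Cd48 passed neither without the block nor with it (adjusted p = 0.0825 and 0.111 with it), so chance is not excluded for them. A larger share of Flt3-expressing multipotent progenitors, which a CD48-negative gate would mostly remove, would lower genes restricted to stem cells. The mean of 8 such genes (Procr, Vwf, Mecom, Fgd5, Hoxb5, Ctnnal1, Mllt3 and Slamf1), chosen after values were seen, was 0.39 higher (95% interval 0.17 to 0.61), but Vwf and Procr carried it, and without them the mean of the other 6 was 0.12 higher (95% interval -0.11 to 0.36). A larger share of progenitors therefore cannot be told apart from a response of the stem cells themselves or a mixture of both.

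Of 192 groups of 5 arrays examined, 14 had an array far from the others, and chance alone gives about 1 in 20 groups. Transgenic array 4 stood apart in the sex-linked genes, with Xist at 4.32, Eif2s3y at 9.23, Kdm5d at 7.85 and Uty at 6.97 against 10.8 to 11.4, 2.60 to 2.75, 3.60 to 3.88 and 2.86 to 3.17 on the other transgenic arrays. Wild-type array 4 stood apart in Uty (3.58 against 2.89 to 3.02), Flt3 (6.14 against 7.10 to 7.48), Pdgfc (5.02 against 5.34 to 5.45) and the sort marker score (-0.69 against -0.19 to -0.07). Transgenic array 2 stood apart in Cd53 (8.44 against 9.45 to 9.75), Ifitm1 (11.6, the lowest of its group) and Lyz2 (9.08 against 8.57 to 8.70). Wild-type array 1 read 10.96 for Ifitm1 against 11.3 to 11.4. Plagl1 read 9.61 on transgenic array 3 against 6.19 to 6.30, and the glycolysis score was -0.16 on transgenic array 5 against 0.03 to 0.09.

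Among the probe sets with no listed gene, which the comparison left out, 1 passed the threshold when all probe sets were tested together (limma, Benjamini-Hochberg). It was 1.31 higher on the transgenic arrays (SE 0.16, adjusted p = 0.0358), at 7.36 against 6.04, and which transcript it reads was not determined here.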

How the results depend on the processing

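The fits with the array sets, without the male array and with the first residual component as covariate were chosen after seeing the data; the other settings were fixed beforehand. Sox17 was not called under any of the alternatives that gave a value, with log2 changes of 0.08 to 0.20; among the brighter probe sets it gave none, since its probe set was filtered out. The stricter threshold, the minimum fold and the Welch test were run only for counts and are not among the values per gene that follow. The Welch test passed 1 probe set, so Rasgrp3 and Gimap4 did not both pass it. In the other alternatives, the 20 named genes past the threshold kept their direction in all 480 values and stayed past it in 324. Rasgrp3 and Gimap4 stayed past it in each of their values there. The 45 other named genes kept direction and side of the threshold in 1031 of 1072 values, passed it in 33 and turned in 8. The 10 called lists kept their direction in all 280 values and were past the threshold in 234, and of 418 values for the other 15 lists 366 were on the same side with the same direction, 22 past the threshold and 30 turned. Signal over background limits the dim probe sets, Sox17 and the embryonic globins among them. The cause of the shifts below was not tested, except where fewer arrays, more probe sets, a stricter rule or a floor lowers a count by construction.

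The replicate numbers gave no clear pairing of the arrays. Same-numbered arrays correlated at 0.241, 0.347, -0.140, 0.109 and 0.328 in their deviations from the group means, and those numbered 3 lie in different array sets. Of the arrays, 0 transgenic and 1 wild-type correlated best with their own number. With the replicate block 33 probe sets passed, 18 of them shared with the 33 of the unpaired fit, and 11 of the 17 genes named by size of change.

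Testing all probe sets gave 15 probe sets (14 higher, 1 lower) and 9 of those 17 genes. The intensity trend with robust eBayes gave 3 lower, the floor 5 higher and 0 lower (4 of the genes), the threshold of 0.01 gave 7 higher and 0 lower (5 of the genes), and the Welch test gave 1 higher and 0 lower (1 of the genes). The array set block gave 91 (73 higher, 18 lower). The surrogate variable gave 97 (76 higher, 21 lower) and the first residual component 121 (92 higher, 29 lower). In each of these fits, the array set block included, a covariate taken from the values lowers the residual spread by construction. Set A alone gave 4 higher and 0 lower (3 of the genes), set B alone 6 higher and 0 lower (4 of the genes), and the block without the male array 10 of the genes. Leaving out 1 array at a time gave 15 to 71 probe sets, 14 to 65 higher and 1 to 6 lower, and 9 to 17 of the genes.

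Of genes not called, Hbb-y was at -0.0302 and Cd244a at -0.11 within set A, Hmga2 at -0.0724 and Hba-x at -0.0591 within set B, and Hbb-y at -0.0381 with the block and without the male array. Leaving out 1 array gave -0.0114 to 0.10 for Hbb-y, -0.0145 to 0.25 for Cd244a and -0.0486 to 0.31 for Slamf1. It also gave 0.42 to 1.28 for Plagl1, 0.66 to 1.54 for S100a8, 0.36 to 0.75 for Cd68, 0.48 to 0.96 for Fos, -0.46 to -0.21 for Aurkb, 0.15 to 0.35 for Hmga2 and 0.12 to 0.27 for Cd34.

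Of the lists, given as adjusted p, the adult HSC list was at 0.0649 after quantile normalization, where ribosome biogenesis was called (0.0478). Among the brighter probe sets it was at 0.0770 and the sort markers at 0.380, while the B cell (0.380), T and NK cell (0.925) and p53 (0.459) lists turned direction and the endoderm list was called higher (0.0233). Array weights put the sort markers at 0.0629, and the floor turned the mast cell list (0.958) and called the Wnt list (0.0482). With the array set block the cholesterol list turned (0.793), and the Wnt (0.0196), ribosome biogenesis (0.0156) and interferon (0.0480) lists were called. With the surrogate variable the cholesterol list turned too (0.786), and the same 3 lists were called (0.0194, 0.0161 and 0.0331). Within set A the adult HSC list was at 0.0522, the sort markers at 0.350 and lymphoid priming at 0.0960, and the B cell (0.894), T and NK cell (0.772), glycolysis (0.669) and cholesterol (0.917) lists turned, while the Wnt (0.0195), ribosome biogenesis (0.000349) and interferon (8.40e-08) lists were called. Within set B 5 lists were called, with the adult HSC, megakaryocyte and endothelial lists at 0.224, lymphoid priming at 0.0651 and immediate early genes at 0.684, and the endoderm (0.892), interferon (0.406), p53 (0.874), cholesterol (0.816) and oxidative phosphorylation (0.964) lists turned. With the block and without the male array the adult HSC list was at 0.0916, and the B cell (0.895), glycolysis (0.531) and cholesterol (0.487) lists turned, while the Wnt (0.0204), ribosome biogenesis (0.00180) and interferon (8.87e-05) lists were called.

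Camera with an estimated correlation called 1 list, the erythroid one, with adult HSC at 0.180, sort markers 0.379, mitosis 0.526, DNA replication 0.0762, megakaryocyte 0.389, granulocyte 0.195, lymphoid priming 0.0844, endothelial 0.379 and immediate early genes 0.478. With the block as well it called 2, erythroid and DNA replication, with adult HSC, endothelial and immediate early genes at 0.347, sort markers 0.373, mitosis 0.528, megakaryocyte and granulocyte 0.171 and lymphoid priming 0.170, and cholesterol turned (0.870). Fry called 3, erythroid, lymphoid priming and DNA replication, with adult HSC at 0.145, sort markers 0.274, mitosis and immediate early genes 0.405, megakaryocyte and endothelial 0.219 and granulocyte 0.225, and p53 turned (0.877). Leaving out 1 array gave 0.00821 to 0.176 for the adult HSC list, 0.00349 to 0.142 for sort markers, 0.00593 to 0.148 for megakaryocyte, 0.000450 to 0.0554 for granulocyte, 0.00821 to 0.295 for Wnt, 0.00694 to 0.452 for ribosome biogenesis, 0.0152 to 0.909 for interferon, 0.501 to 0.995 for p53, 0.229 to 0.998 for cholesterol and 0.503 to 0.989 for imprinted genes.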

Other observations

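The tests in this part were chosen after the values were seen, except the one on neighbouring genes.

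Genes of the GIMAP family, small GTPases of lymphocytes that lie side by side in the genome, were higher on the transgenic arrays as a group. Gimap4 rose 3.78-fold and Gimap6 2.08-fold (limma adjusted p = 0.000177 and 0.00326), and Gimap3 was 2.05 log2 units higher (SE 0.34, adjusted p = 0.0527). All 6 members other than Gimap4 and Gimap6 had positive changes, with a median of 0.67 (0.64 after quantile normalization and 0.68 with arrays centred on the median), and with the array set as a block 6 of the 8 passed the threshold. A rise of the whole family is a hypothesis with which the other 6 members are in line (camera p = 0.000468 with an estimated correlation, 0.000124 with the array set as a block).

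Of the genes known as targets of STAT5, the transcription factor downstream of several blood cytokine receptors, Cish and Csf2rb rose. Cish, a cytokine-induced inhibitor of signalling, rose 2.17-fold and Csf2rb, the common beta chain of the GM-CSF, IL-3 and IL-5 receptors, 2.40-fold (limma adjusted p = 0.0447 and 0.00831), while Socs2 was 2.19 log2 units higher (SE 0.39, adjusted p = 0.0743) and Csf2rb2, a near-copy of Csf2rb that its probes may not tell apart, 1.03 (SE 0.20); both passed with the array set as a block (adjusted p = 0.0476 and 0.0161). The 9 other target genes tested, Socs1, Socs2, Socs3, Pim1, Osm, Bcl2l1, Bcl6, Id1 and Ccnd2, rose as a set (camera p = 0.0235 with an estimated correlation), but with the array set as a block p was 0.0528 and the call was lost. Of the 9, 7 were positive, Socs1 and Bcl6 by only 0.05 and 0.04, and Ccnd2 and Bcl2l1 differed by -0.15 and -0.19, with a median of 0.24 (0.22 after quantile normalization and 0.25 with arrays centred on the median), and Csf2rb2 was left out as a near-copy after a first run that held it. Socs2 had by far the largest change of the 9, the next being 0.29 for Osm, so a rise of STAT5 targets as a group stays open. The receptor S1pr1, which guides leukocytes between blood and tissue, also rose, 1.96-fold (adjusted p = 0.0184).

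The 2 probe sets shared by adult beta-globin genes rose while most erythroid genes were lower. More red cell RNA in the transgenic aliquots would raise alpha-globin alike, if its probe sets respond as the beta-globin ones do. The mean of the 2 alpha-globin probe sets differed by -0.40 (95% interval -1.50 to 0.70), below the smaller beta-globin change of 2.04. On the transgenic arrays the alpha-globin probe sets averaged 6.15 and 6.21 and the beta-globin ones 11.2 and 11.1. An equal response was not tested, so the comparison cannot decide on red cell RNA. A sequence difference between beta-globin haplotypes of mouse strains was not tested.

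Linked loci around an inserted transgene or carried-over strain segment could place called genes next to each other. Of 30 called genes, 1 pair lay within 10 genes of each other in gene order, Gimap4 and Gimap6, and 0.354 of 10000 random draws had at least as many pairs, so such a segment cannot be told apart from chance placement with this test.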
